A study of Mus musculus with 2 samples.

How the data were processed

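Single-cell RNA sequencing was analysed for 2 libraries of mouse quadriceps cells, 1 from muscles treated with nanoparticles carrying AICAR and 1 from muscles treated with nanoparticles carrying vehicle. Per the labels' protocols, each thigh muscle of C57BL/6J mice received a 3 mm biopsy-punch defect, the particles were given at the wound on days 1, 4 and 7, and tissue was taken on day 8. Muscles of 1 treatment were pooled before digestion with collagenase II and dispase II, red cells were lysed, DAPI-positive cells were sorted away, and the cells of each treatment carried their own multiplexing oligo, per the labels' protocols. The number of mice in each pool is not given in the sources used here. A pool is 1 sample, so each group had n = 1 and the design holds no replicate.

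The deposited values are raw UMI counts per gene and barcode, made by the authors with Cell Ranger 8.0.0 on the mouse build GRCm39, per the submitters' processing notes. The annotation release is not given in the sources used here. Each file lists 33696 genes and only barcodes called as cells by the authors' software, with a minimum of 500 UMIs in both libraries. No further normalization or filter of the deposited counts was found: all values were whole numbers of at least 1. The AICAR library held 14278 barcodes and 170614683 UMIs, and the vehicle library 16642 barcodes and 191259125 UMIs. The 2 libraries shared 77 barcode sequences. No annotation of cell types was used from the authors.

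From these counts, barcodes with at least 200 genes and at most 10% of UMIs from mitochondrial genes were kept. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5, with its automatic threshold. That threshold marked 1.43% of barcodes in the vehicle library and 0% in the AICAR library. By a rule fixed in advance for a caller that marks under 0.5%, the highest 5% of scores were removed from the AICAR library instead, 528 barcodes against 152 in the vehicle library, so doublet removal was unequal. The rule can also be read as removing the highest 5% from both libraries, and that reading is carried as an alternative. The kept cells, 9792 and 10489, were clustered together without integration (10000 counts per cell, log1p, 2000 variable genes, 30 principal components, 15 exact nearest neighbours, Leiden resolution 1 with leidenalg 0.10.2), which gave 29 clusters. Marker lists for 19 cell classes, 35 gene lists, the rule for named genes, the filters, the clustering settings and 11 alternative settings were chosen before the data were examined. The scoring rule for cluster names was written afterwards. A cluster took the class with the most enriched markers, at least 3, where a marker counted if detected in at least 25% of the cluster's cells and at least 2-fold above the other cells with 5 CPM added. It stayed unnamed if its 10 leading genes held more markers of another class than of its own, if its first gene was a marker of another class, or if its median UMI count was under 1/3 of that of its sample with no own marker among the 10. Named clusters are called "like" their class throughout.

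Counts were summed per library and class and expressed as CPM with the class total as denominator. The ratio of CPM, AICAR over vehicle, has an exact 95% interval for 2 Poisson counts, and a share of cells has an exact Clopper-Pearson 95% interval (scipy 1.17.1). Both cover counting error only, not differences between animals, pools or captures. No p-value was computed, because cells of 1 pool are not replicates. Genes were counted by size alone: at least 1.5-fold higher or lower among genes with a CPM of at least 30 in at least 1 library. For each gene list the median log2 ratio was taken over members with at least 50 UMIs in the class, with an exact order-statistic 95% interval over the members, a counting interval from 1000 Poisson draws, and the percentile of the median among 10000 random lists of the same size matched on mean expression. That percentile is a description of these 2 libraries, because the random lists do not keep any joint movement of a list's members. Members were counted as higher or lower at 1.25-fold, by size alone. Only part of the class and list combinations is reported. These were chosen after the medians had been seen, to cover each list at least once, to compare 3 lists between classes and to give markers of other cell types beside the genes they move with. Alternatives were run for 63 of them.

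Named genes were chosen by rank of log2((CPM + 1)/(CPM + 1)) among genes with a CPM of at least 30 in either library and at least 100 UMIs over both: the 12 highest and 12 lowest in macrophage-like and fibroblast-like cells, and the 5 highest and 5 lowest in each other class with at least 50 cells per library. Mitochondrially encoded genes, ribosomal proteins, haemoglobins, immunoglobulin genes, sex-linked genes, predicted models and genes with over 10 times the CPM in another class were left out. From each gene list, 2 to 4 members with a high CPM or a large ratio are also named. Some genes that met these rules, and 1 test on 1 of them, are not reported here. A class whose gene had 0 counts in 1 library is compared with a floor of 3 counts in that library. Genes marked as open to free RNA had over 10 times the CPM in another class.

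The ratio, size and list steps were tested on simulated data with 200 changed genes. In the simulation of macrophage-like cells (4775 genes), all genes set 2-fold apart passed the 1.5-fold size rule, as did 32% of those set 1.5-fold higher and 54% of those set 1.5-fold lower. The counting intervals held the true value for 95.7% of unchanged genes there, and for 95.3% in the simulation of fibroblast-like cells (5126 genes). None of the unchanged genes passed the size rule in either simulation. For fibroblast genes set 1.5-fold higher, the intervals held the true value in 88% of them. Both simulated libraries were Poisson counts around the same means, so these outcomes check the computation and largely follow from the setup. The simulation held no variation between pools, captures or cells, and so cannot gauge how far 2 real libraries of 1 treatment would differ.

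Alternatives fixed in advance were a stricter cell filter (500 genes, 5% mitochondrial UMIs), doublet calls kept in, Leiden resolution 0.5 or 2, 4000 variable genes with 50 components, TMM factors from edgeR 4.0.16 as scaling of the counts, the mean of each cell's own CPM, cells thinned to 3000 UMIs, no minimum count, genes open to free RNA left out, and clusters with over 80% of cells from 1 library left out. A further 6 alternatives were chosen after the data had been seen: equal doublet removal, monocyte and macrophage clusters joined with the unnamed cluster led by interferon genes (called combined, without the shallow haemoglobin cluster), clusters of a class weighted alike in both libraries, erythroid and unnamed clusters left out of the denominator, and looser naming rules for the clustering with doublets and for that with the stricter filter. Shared sequence between genes was searched in transcripts of the older build GRCm38 (GENCODE vM21) as sequence only, and no coordinates are reported because the build of the files was not used here.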

Results

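Cells from quadriceps muscle of mice with a volumetric muscle injury were profiled by single-cell RNA sequencing on day 8, after local nanoparticles that carried either AICAR, an activator of AMP-activated protein kinase, or vehicle. Each group is 1 library made from pooled muscles. The AICAR library held 14278 barcodes with a median of 10512 UMIs and 2599.5 genes, and the vehicle library 16642 barcodes with a median of 9058.5 UMIs and 1977 genes. Barcodes with under 200 genes made up 21.9% of the AICAR library and 31.6% of the vehicle library, and nearly all of them were red-cell barcodes with most UMIs from haemoglobin genes (3121 of 3122 and 5245 of 5256). After filters and doublet removal 9792 and 10489 cells remained. All differences below are between 2 libraries, so no difference has a replicate check. Intervals of shares and of single-gene ratios cover counting error only. Those of list medians run over the members of the list.

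Which cell types made up the suspension, and did their shares differ between the libraries? NK-like, T-like, neutrophil-like and dendritic-like cells took a smaller share of the AICAR library, while mural-like, myogenic progenitor-like and fibroblast-like cells took a larger one. NK-like cells were 3.59% (3.23–3.98) of kept cells in the AICAR library and 8.79% (8.26–9.35) in the vehicle library, a ratio of 0.409 [0.361–0.463]. T-like cells were 4.18% (3.79–4.59) against 8.53% (8.00–9.08), ratio 0.490 [0.434–0.551], neutrophil-like cells 5.70% (5.25–6.18) against 8.79% (8.26–9.35), ratio 0.648 [0.583–0.721], and dendritic-like cells 7.72% against 10.1%, ratio 0.768 [0.698–0.844]. Mural-like cells were 3.65% (3.28–4.04) against 1.63% (1.40–1.89), ratio 2.24 [1.86–2.70]. Myogenic progenitor-like cells were 5.40% (4.96–5.87) against 3.59% (3.25–3.97), ratio 1.503 [1.31–1.72], and fibroblast-like cells 8.07% (7.54–8.62) against 5.62% (5.18–6.07), ratio 1.44 [1.29–1.60].

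Macrophage-like cells had a similar share in both libraries, 23.1% (22.2–23.9) and 22.8% (22.0–23.6), ratio 1.01 [0.955–1.07]. Over the alternatives this ratio ranged from 0.997 to 1.12, and it lay above that interval under every other clustering. Monocyte-like cells were 6.17% against 6.61%, ratio 0.934 [0.836–1.04]. The ratio turned to 1.18 at Leiden resolution 2, where a cluster led by interferon genes was named monocyte. In the main clustering a cluster led by these genes stayed unnamed and held 11.2% of the AICAR library and 6.65% of the vehicle library. Together with the monocyte and macrophage clusters (below called combined) it made 40.4% against 36.1%, ratio 1.12 [1.07–1.17]. Unnamed clusters in all held 15.3% and 10.5%, among them a shallow cluster of macrophage markers with haemoglobin (3.83% and 3.66%) and a small cluster of lymphatic markers (32 and 20 cells). Endothelial-like cells were 6.89% against 5.87%, ratio 1.17 [1.05–1.31], and B-like cells numbered 127 and 164, ratio 0.830 [0.653–1.05].

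**Figure D1:**
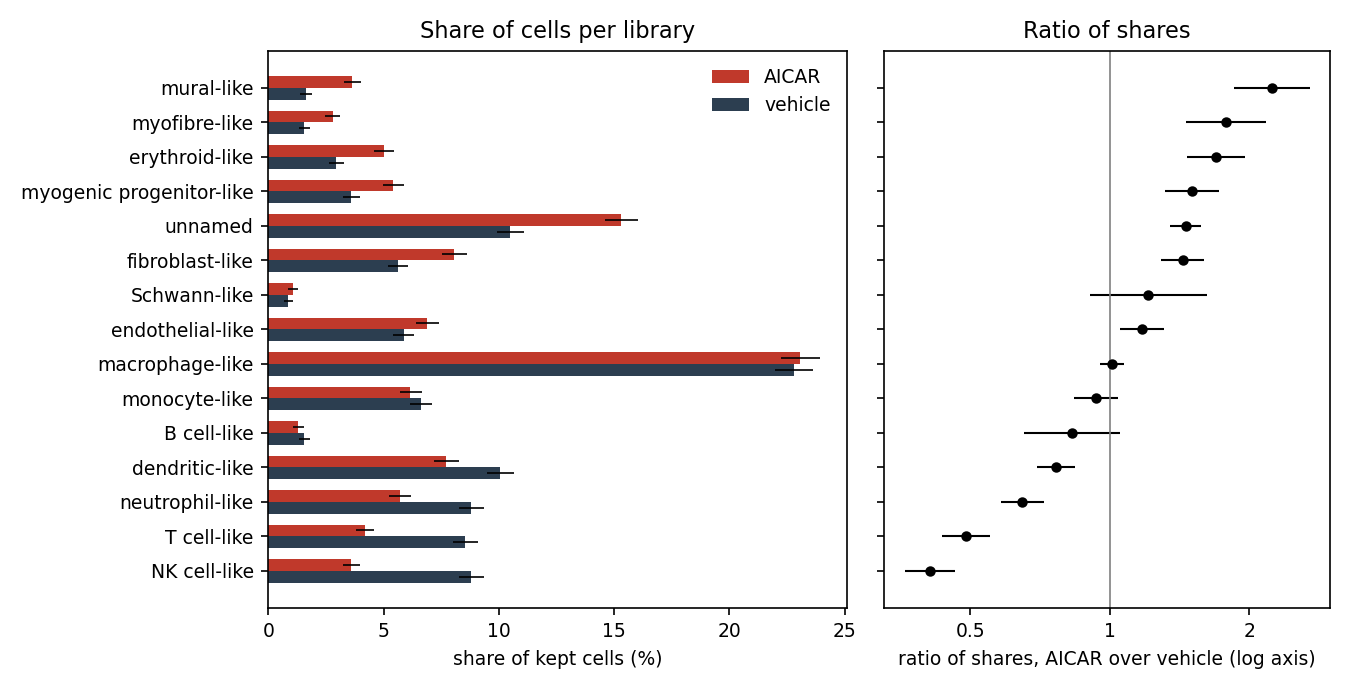
Share of kept cells per cell class in the AICAR and the vehicle library with exact 95% intervals (left), and the ratio of shares, AICAR over vehicle, on a log axis with its interval (right). Error bars show counting error only; NK-like cells had the lowest ratio with at least 50 cells per library (0.409) and mural-like cells the highest (2.24).

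The fibroblast and neutrophil shares depended on the naming of clusters. With doublet calls kept in, the fibroblast ratio turned to 0.851, because the largest fibroblast cluster then lost its name when the tenocyte marker Thbs4 led it, and only 472 of 1379 fibroblast-like cells kept the name. With that cluster named the ratio was 1.56. With the stricter cell filter the neutrophil ratio was 0.867, but a neutrophil cluster of 149 and 391 cells then lost its name as shallow, and with it named the ratio was 0.675. Shares are relative to each other, and the cells come from 1 digestion per group.

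Did macrophage-like cells differ in their transcripts? Spp1 had the highest ratio among the genes reported here, and Ccl8, Arg1 and Retnla were among the lowest in the AICAR library. By size alone, 50 genes were at least 1.5-fold higher and 33 at least 1.5-fold lower of 4911 genes with a CPM of at least 30. Spp1 (ENSMUSG00000029304), which encodes the matrix protein osteopontin, stood at 1136 CPM in the AICAR library and 504 CPM in the vehicle library, ratio 2.26 [2.22–2.29]. Fcrls (166 against 80.7 CPM, 2.05), Lyz1 (67.7 against 34.7 CPM, 1.95), Apoc2 (122 against 67.4 CPM, 1.81), Hpgd (107 against 61.0 CPM, 1.76) and Reps2 (73.7 against 41.2 CPM, 1.79) were also higher. Coro1b (38.0 against 17.2 CPM, 2.21), Lars2 (375 against 177 CPM, 2.12), Cmss1 (1155 against 626 CPM, 1.85), Gstp1 (63.3 against 35.0 CPM, 1.81) and the heat shock gene Hspa1a (358 against 211 CPM, 1.69) were also among the 12 highest. Gstp1 was at least 1.5-fold higher in 12 of the 12 classes with at least 50 UMIs of it. The same held for Ube2s (12 of 12) and H2ac18 (11 of 12), which are named in other classes below. Lars2 and Cmss1 were also among the 5 highest genes in erythroid-like cells (1.64 and 1.36). Their direction was thus not particular to macrophage-like cells.

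Among the lower genes, the monocyte chemokine gene Ccl8 (ENSMUSG00000009185) stood at 580.1 CPM in the AICAR library and 1454 CPM in the vehicle library, ratio 0.399 [0.393–0.405]. Arg1 (ENSMUSG00000019987), which encodes arginase, stood at 153 against 311 CPM, 0.493 [0.477–0.508], and Retnla (ENSMUSG00000061100), a gene of alternatively activated macrophages, at 117 against 236 CPM, 0.495 [0.478–0.513]. Of genes that interferon gamma induces, these were also among the 12 lowest: Gbp2 (ENSMUSG00000028270) 36.5 against 94.0 CPM, 0.388 [0.365–0.413], Cxcl9 (ENSMUSG00000029417) 33.3 against 72.2 CPM, 0.461 [0.431–0.493], Gbp8 15.6 against 32.6 CPM, 0.478, and Ly6a 175 against 347 CPM, 0.505. Nrg1 (ENSMUSG00000062991; 79.5 against 165 CPM, 0.481), Naaa (136 against 254 CPM, 0.534), Tppp3 (68.5 against 126 CPM, 0.544), Ltb4r1 (20.9 against 36.7 CPM, 0.569) and Wdr89 (22.9 against 39.6 CPM, 0.579) complete the 12 lowest.

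**Figure D2:**
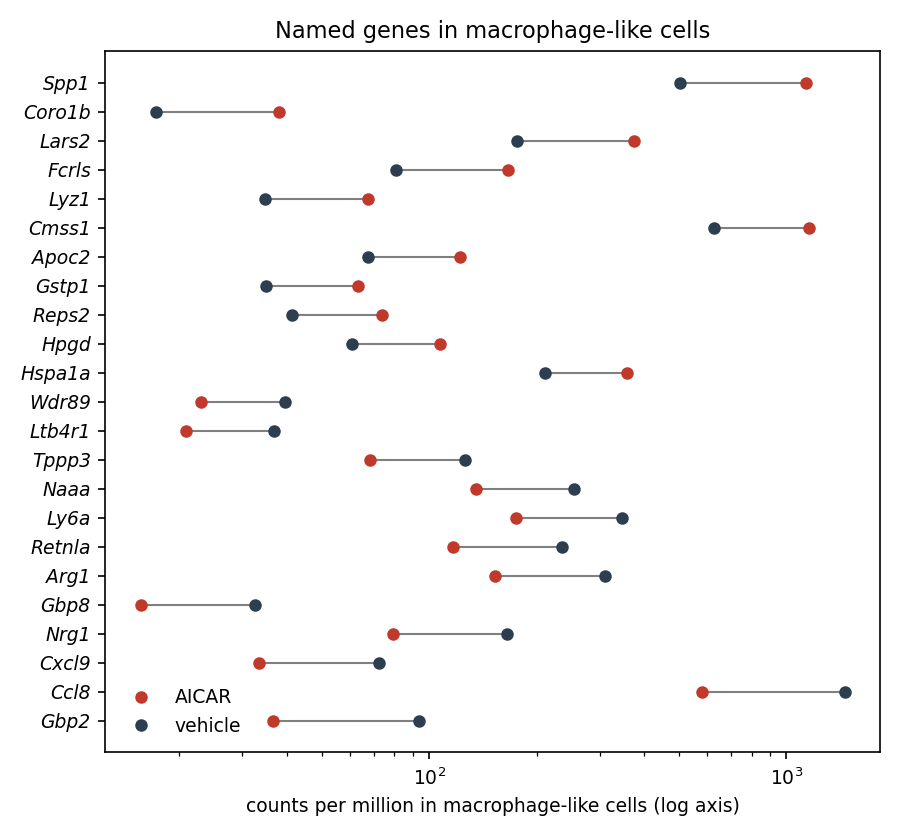
CPM of the named genes reported here in macrophage-like cells, on a log axis, in the AICAR and the vehicle library. There are no error bars because each point is 1 library; Spp1 stood at 1136 against 504 CPM and Ccl8 at 580.1 against 1454 CPM.

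Different clusters led the class in the 2 libraries: cluster 2, marked by Fcrls, Ms4a7, Apoe and C1qa, held 840 of 2260 macrophage-like cells in the AICAR library, and cluster 0, led by Clec4b1, held 1039 of 2392 in the vehicle library, while Arg1, Spp1, Ccl8 and Ccl24 led cluster 3. With clusters weighted alike, the log2 ratio was 1.20 for Spp1 (1.17 without), −0.86 for Arg1 (−1.02), −1.44 for Ccl8 (−1.32) and 0.67 for Fcrls (1.03). Spp1 and Retnla kept their direction in 2 of 3 clusters and the other named genes in all 3. In the combined cells the log2 ratio of Gbp2 was −0.32 in place of −1.34 and that of Ly6a −0.37 in place of −0.98. That of Ltb4r1 was −0.43 in place of −0.78. With doublet calls kept in it was −1.44, but the class changed too: a large cluster with Clec4b1 was then named monocyte, and 60.8% of macrophage-like cells kept their name.

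Was energy metabolism different in macrophage-like cells? The medians of the glycolysis list and, slightly, of nuclear-encoded respiratory genes lay below 0 in the AICAR library, and that of mitochondrially encoded subunits above 0. The glycolysis list had a median log2 ratio of −0.25 (95% interval over the members −0.35 to −0.08), below all of 10000 matched random lists, with 0 members higher and 5 lower of 19 by the size rule for lists. Examples are the lactate exporter Slc16a3 (45.7 against 63.5 CPM, 0.719), Pfkp (86.8 against 111 CPM, 0.780), Tpi1 (155 against 194 CPM, 0.800) and Gapdh (889 against 1102 CPM, 0.807). The medians of the tricarboxylic acid cycle (−0.12, 0 higher and 0 lower of 21, percentile 3.64, with Cs at 50.4 against 60.6 CPM) and of nuclear-encoded oxidative phosphorylation (−0.10, interval −0.12 to −0.08, percentile 0.02, 0 higher and 0 lower of 72, with Cox4i1 at 777 against 804 CPM and Ndufa4 at 324 against 345 CPM) lay slightly below that of all genes, −0.05. Mitochondrially encoded subunits had a median of 0.22 with 5 higher and 0 lower of 13, led by mt-Nd4l (250 against 137 CPM, 1.82) and mt-Co1 (4398 against 3468 CPM, 1.27), and mitochondrial UMIs made 2.37% of the class in the AICAR library and 2.01% in the vehicle library. This direction was not particular to macrophage-like cells. The list also stood at 0.09 in fibroblast-like, 0.15 in myogenic progenitor-like and 0.07 in endothelial-like cells. The gene mt-Nd4l was at least 1.5-fold higher in 10 of 13 classes.

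Fatty acid oxidation had a median of −0.16 with 0 higher and 3 lower of 20, among them Cpt1a, which controls entry of fatty acids into mitochondria (39.6 against 55.9 CPM, 0.708). Genes of the AMPK subunits and mitochondrial biogenesis had a median of −0.08, percentile 28.8, with 1 member lower of 17, Ppargc1b (12.2 against 18.5 CPM, 0.656). Purine metabolism, the pathway AICAR enters, had a median of −0.13 with 1 higher and 2 lower of 22. Gda stood at 197 against 272 CPM (0.727) and Atic had a ratio of 0.815. Lipid uptake, storage and efflux had a median of 0.06 with 4 higher and 0 lower of 17, led by Apoe (14222 against 9181 CPM, 1.55) and Trem2 (370.4 against 289.7 CPM, 1.28). Fatty acid and sterol synthesis had a median of 0.09 with 3 higher and 2 lower of 19. The hypoxia list had a median of −0.11 with 1 higher and 1 lower of 14, and Vegfa was its higher member (86.4 against 61.2 CPM, 1.41).

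How did activation lists compare? The medians of the inflammatory and efferocytosis lists lay above 0, and the alternative activation list was split. Of the inflammatory members 11 of 24, and of the efferocytosis members 12 of 15, did not pass the size rule for lists. Inflammatory cytokines and NF-kB targets had a median of 0.22 (interval 0.10 to 0.44) with 10 higher and 3 lower of 24, such as Ccl4 (836 against 457 CPM, 1.83), Acod1 (32.9 against 15.9 CPM, 2.07) and Cxcl2 (1616 against 1194 CPM, 1.35), with Ccl5 lower (46.7 against 76.9 CPM, 0.608). Of its 24 members, 11 had over 10 times the CPM in another class and are open to free RNA, among them these 4. Without them the median was 0.12. Efferocytosis and complement C1q had a median of 0.19 (interval 0.12 to 0.30) with 3 higher and 0 lower of 15, led by Stab1 (123 against 93.8 CPM, 1.31) and Gas6 (60.5 against 46.9 CPM, 1.29), and a median of 0.12 in the combined cells. The lipid-associated and scar-associated list had a median of 0.19 (interval −0.04 to 0.35) with 5 higher and 1 lower of 18, with Gpnmb (159 against 124 CPM, 1.28) and Cd9 (308 against 217 CPM, 1.42) higher and Ctsk lower (108 against 141 CPM, 0.767), and its median ranged from −0.01 to 0.29 over the alternatives.

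Alternative activation and repair had a median of −0.03 (interval −0.40 to 0.25) with 4 higher and 6 lower of 20. Gdf15 (165 against 102 CPM, 1.62) and Il10 (46.6 against 31.5 CPM, 1.48) were higher, while Mrc1 (759 against 1038 CPM, 0.731) and Ccl24 (90.4 against 148 CPM, 0.613) were lower beside Arg1 and Retnla. NRF2 and iron handling had a median of 0.06 with 3 higher and 2 lower of 15, with Slc7a11 higher (115 against 71.0 CPM, 1.62) and Hmox1 lower (212 against 319 CPM, 0.665), and the median turned to −0.01 with doublet calls kept in and the class changed as above. Chemokines and growth factors for stroma had a median of 0.08 with 3 higher and 1 lower of 19, with Thbs1 higher (514 against 396 CPM) and Ccl8 lower, and ranged from −0.01 to 0.12 over the alternatives. MHC class II (median −0.01, 0 higher and 0 lower of 9, H2-Aa 5336 against 5178 CPM), lysosome and autophagy (−0.02, 2 higher and 0 lower of 25, Lamp1 811 against 793 CPM) and cell cycle (−0.04, 0 higher and 1 lower of 21, 13 of them open to free RNA, Mki67 9.07 against 10.8 CPM) lay near 0.

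Signs of dissociation stress and of free RNA moved with the group. Immediate early and stress genes had a median of 0.24 with 8 higher and 0 lower of 18 in macrophage-like cells, such as Egr1 (347 against 216 CPM, 1.60) and Jun (776 against 515 CPM, 1.51). Collagen transcripts, all 15 of them over 10 times more abundant in another class, had a median of 0.51 with 13 higher and 0 lower.

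Did interferon genes differ in monocytes, macrophages and neutrophils? Type I interferon response genes were higher in the AICAR library in the combined cells and in neutrophil-like cells, and the size in macrophages depended on where the interferon cluster was placed. In macrophage-like cells alone the list had a median of 0.12 (interval −0.15 to 0.36) with 6 higher and 2 lower of 21, with Ifit3 higher (28.1 against 17.9 CPM, 1.57). In the combined cells the median was 0.76 (interval 0.38 to 1.01) with 17 higher and 0 lower of 21, and 0.38 with clusters weighted alike. Slfn4 (168 against 55.2 CPM, 3.04 [2.93–3.16]), Ifit2 (ENSMUSG00000045932; 223 against 88.5 CPM, 2.52 [2.44–2.60]) and Isg15 (721 against 359.9 CPM, 2.00 [1.97–2.03]) were among its highest genes, and by size alone 59 genes were higher and 16 lower of 4887. With that weighting the log2 ratio of Ifit2 was 0.89 in place of 1.32. MHC class II in the combined cells had a median of −0.26 with 0 higher and 4 lower of 9, such as Ciita (70.6 against 96.7 CPM, 0.730).

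Monocyte-like cells had 37 genes higher and 49 lower by size alone of 4875. MHC class II was lower with a median of −0.57 (interval −0.81 to −0.46) and 8 of 8 members, such as H2-Ab1 (2320.1 against 3743 CPM, 0.620), Cd74 (6028 against 8930.2 CPM, 0.675) and Ciita (52.1 against 92.2 CPM, 0.566), and the median was −0.19 with doublet calls kept in, when the class had taken in the Clec4b1 cells. Cxcl9 (8.52 against 42.9 CPM, 0.199 [0.153–0.254]), Ly6a (115 against 296 CPM, 0.391), Psd3 (21.3 against 60.5 CPM, 0.353) and Qpct (12.4 against 32.8 CPM, 0.377) were lower. The log2 ratios of these 4 genes depended on the clustering. That of Cxcl9 was −0.40 with doublet calls kept in (−2.21 before). At Leiden resolution 2 that of Ly6a was −0.15 in place of −1.35, that of Psd3 −0.71 in place of −1.46 and that of Qpct −0.43 in place of −1.34. Arg1 was lower too (25.2 against 74.4 CPM, 0.339), but its log2 ratio of −1.53 turned to 0.53 at Leiden resolution 2 and to 1.05 with 4000 variable genes. In both of these settings a cluster led by interferon genes was named monocyte, so the class changed too. Coro1b (2.62), Gstp1 (2.53), Ube2s (2.45) and Dmkn (40.2 against 16.5 CPM, 2.44) were among the highest, of which Gstp1 and Ube2s were higher in nearly all classes. Glycolysis had a median of −0.24 with 0 higher and 3 lower of 18 (Gapdh 942 against 1157 CPM, 0.814), the interferon list a median of 0.04 but a mean of −0.08 with 1 higher and 3 lower of 20 (−0.21 to 0.93 over the alternatives), and immediate early genes a median of 0.24 with 5 higher and 0 lower of 18.

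Neutrophil-like cells lay in 2 clusters of different mix: cluster 7, led by S100a9 and S100a8, held 4.05% of kept cells in the AICAR library and 5.05% in the vehicle library, and cluster 14 held 1.64% and 3.74%. In these cells the interferon list had a median of 1.11 (interval 0.99 to 1.47) with 18 higher and 0 lower of 19, such as Ifit2 (292 against 48.5 CPM, 6.02 [5.21–6.96]), Isg15 (1274 against 556 CPM, 2.29) and Rsad2 (1626 against 757 CPM, 2.15). The median was 0.68 with the stricter cell filter, where 878 of 1419 neutrophil-like cells kept their name, and 1.08 with the lost cluster named. Tgtp1 (53.8 against 7.60 CPM, 7.08), Trim30c (138 against 27.9 CPM, 4.94), Chil3 (339.5 against 85.0 CPM, 4.00) and H2ac18 (181 against 23.2 CPM, 7.82) were the other highest genes. H2ac18 was at least 1.5-fold higher in 11 of 12 classes, so its direction was not particular to these cells. Granule genes had a median of 0.56 (interval 0.12 to 1.08) with 8 higher and 0 lower of 13, with Camp (2327 against 887 CPM, 2.62) and S100a9 (23502 against 15032 CPM, 1.56). The granule median was 0.29 with clusters weighted alike and 0.27 for the mean of each cell's own CPM, and Chil3 was higher in 1 of 2 clusters. The nuclear receptor gene Pparg (ENSMUSG00000000440; 2.91 against 34.1 CPM, 0.0853), Adgre4 (0.101), S100a1 (0.166), Lrrc14b (0.181) and Wdr89 (0.197) were the lowest. With doublet calls kept in, the log2 ratio was −1.13 for Pparg (−3.17 without) and −0.84 for Adgre4 (−3.03). With the stricter filter and the lost cluster unnamed it was −0.82 for S100a1 (−2.51) and −1.34 for Lrrc14b (−2.30). MHC class II, all 6 members open to free RNA, had a median of −1.32 with 6 of 6 lower. Inflammatory genes had a median of 0.20 with 10 higher and 2 lower of 21 (Il1b 8058 against 5359 CPM), which turned to −0.04 with the stricter filter and was 0.17 with the lost cluster named and 0.085 with clusters weighted alike. Immediate early genes had a median of 0.26 with 8 higher and 1 lower of 18. By size alone 183 genes were higher and 690 lower of 4277, and with TMM factors, which moved all genes by a log2 of 0.25, 407 were higher and 258 lower.

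Did fibroblast-like cells differ? The medians of the glycolysis, cell cycle and contractile lists lay below 0, that of fibrillar collagens slightly below 0, and that of adipogenic genes above 0 with a wide interval. By size alone 160 genes were higher and 125 lower of 5365. Cell cycle genes had a median log2 ratio of −1.52 (interval −1.84 to −1.03), and all 23 members were lower, such as Top2a (5.24 against 49.6 CPM, 0.106) and Mki67 (7.83 against 38.9 CPM, 0.201). This size depended on doublets and on how cells were weighted: it was −0.89 with equal doublet removal, −1.02 with doublet calls kept in and the largest cluster named, and −0.52 for the mean of each cell's own CPM. With doublet calls kept in and that cluster unnamed it was 0.03, in a class that held 34.2% of the former cells. Glycolysis had a median of −0.54 (interval −0.75 to −0.34) with 0 higher and 13 lower of 17, such as Pgk1 (75.5 against 144 CPM, 0.523), Pkm (136 against 233 CPM, 0.582) and Gapdh (362 against 609 CPM, 0.594), and −0.32 with equal doublet removal. The hypoxia list had a median of −0.43 with 0 higher and 8 lower of 13, led by Mif (175 against 336 CPM, 0.521), and −0.20 for the mean of each cell's own CPM.

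Fibrillar and network collagens had a median of −0.23 (interval −0.37 to −0.02) with 3 higher and 5 lower of 18, and −0.058 for the mean of each cell's own CPM. Col1a1 was lower (10627 against 13763 CPM, 0.772), while the basement membrane genes Col4a1 (531 against 303 CPM, 1.75) and Col15a1 (211 against 118 CPM, 1.79) were higher. Matrix crosslinking and turnover had a median of −0.14 with 2 higher and 6 lower of 24 (Loxl2 206 against 301 CPM, 0.683), and −0.035 for that mean. Matrix glycoproteins and proteoglycans had a median of −0.04 with 3 higher and 6 lower of 22, with Tnc (604 against 1008 CPM) and Cthrc1 (963 against 1526 CPM, 0.631) lower and Dcn higher (4900 against 3466 CPM, 1.41), and ranged from −0.12 to 0.08 over the alternatives. Contractile myofibroblast genes had a median of −0.60 (interval −1.17 to −0.20) with 1 higher and 8 lower of 12, 6 of them open to free RNA: Lrrc15 (60.0 against 153 CPM, 0.391), Acta2 (121 against 275 CPM, 0.441) and Tpm2 (122 against 232 CPM, 0.524). That median was −0.32 for the mean of each cell's own CPM, 0.09 with doublet calls kept in and −0.63 when the largest cluster was named as well. The TGF-beta list had a median of 0.07 but a mean of −0.03, with 3 higher and 6 lower of 17, with Ccn2 higher (199 against 119 CPM, 1.68) and Inhba (22.0 against 39.2 CPM, 0.562) and Ltbp1 (113 against 177 CPM, 0.639) lower; the median was 1.22 with doublet calls kept in, 0.094 when the largest cluster was named as well, and 0.25 in thinned cells.

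The adipogenic list had a median of 0.52 (interval −0.05 to 1.09) with 6 higher and 1 lower of 10, such as Lpl (342 against 144 CPM, 2.38), Dlk1 (168 against 78.2 CPM, 2.15) and Cebpd (697 against 377 CPM, 1.85). Of its 10 members, 5 are open to free RNA. Its median was 0.18 for the mean of each cell's own CPM, −0.50 with doublet calls kept in and 0.78 when the largest cluster was named as well. Stromal cytokines and complement had a median of −0.21 with 4 higher and 7 lower of 17: Ccl2 (77.9 against 185 CPM, 0.421) and Ccl7 (143 against 264 CPM, 0.540) were lower and Cxcl14 higher (262 against 139 CPM, 1.89). This median ranged from −0.30 to −0.04 over the alternatives. The uncommitted fibroblast list had a median of −0.20 with 2 higher and 3 lower of 12, with Dpp4 lower (33.5 against 54.0 CPM, 0.620) and Clec3b higher (621 against 453 CPM, 1.37), and was −0.05 at Leiden resolution 2. Immediate early genes had a median of 0.29 with 8 higher and 0 lower of 18 (Jun 2601 against 1796 CPM, 1.45). MHC class II, all 7 members open to free RNA, had a median of −0.27 with 0 higher and 2 lower.

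**Figure D3:**
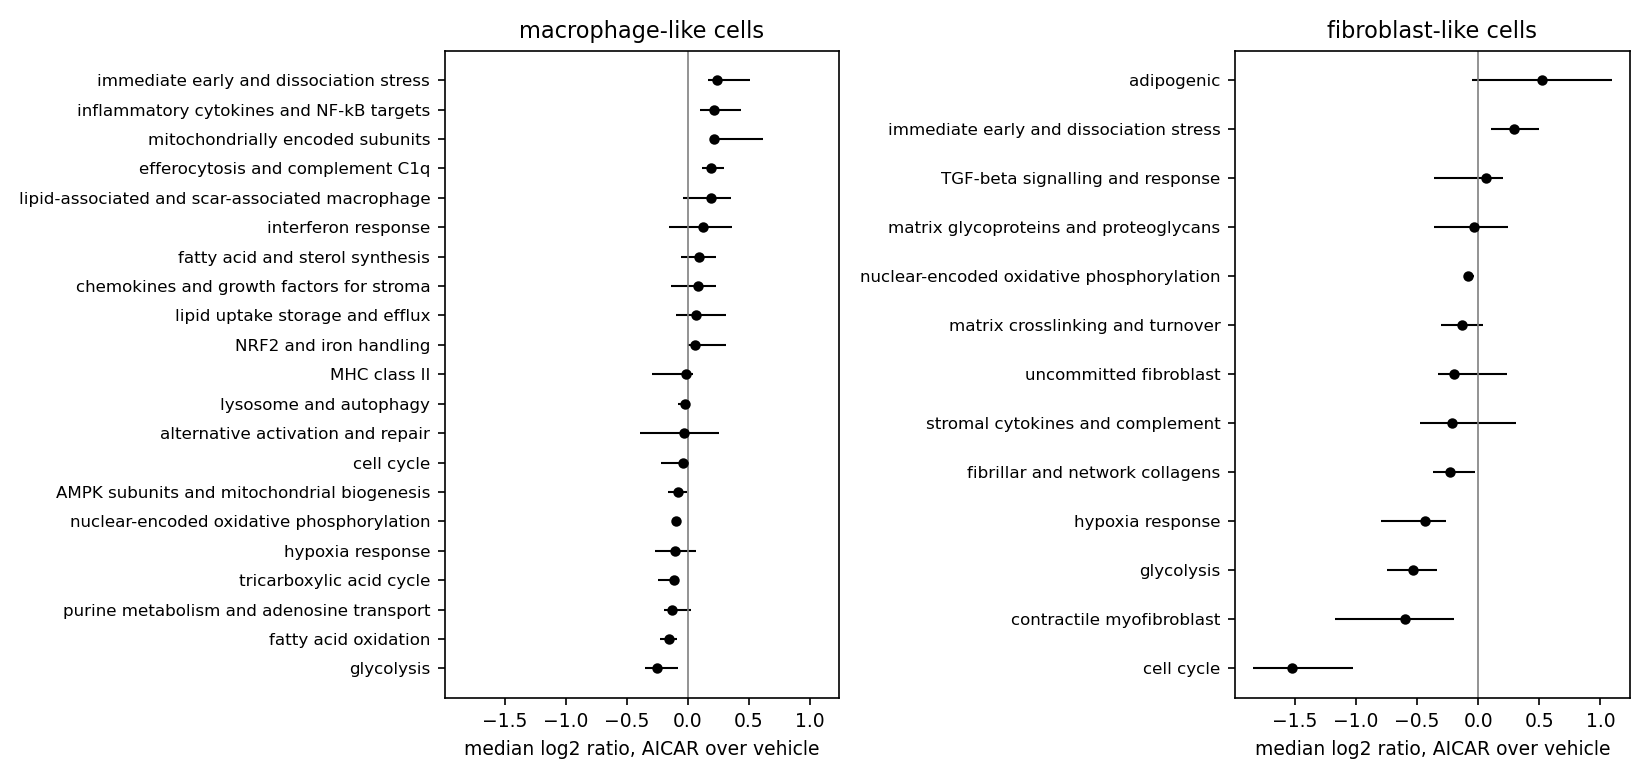
Median log2 ratio, AICAR over vehicle, of gene lists in macrophage-like cells (21 lists) and fibroblast-like cells (13 lists). Bars are 95% intervals over the members of a list; fibroblast cell cycle (−1.52) lay furthest from 0, and macrophage glycolysis stood at −0.25.

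Among single genes of fibroblast-like cells, Smpd3 (ENSMUSG00000031906), which encodes a neutral sphingomyelinase, was lowest in the AICAR library, 4.71 against 55.3 CPM, ratio 0.0852 [0.0656–0.109]. Saa3 (12.5 against 79.5 CPM, 0.157), Actg2 (5.84 against 31.8 CPM, 0.184), Pcdh15 (0.221), Tnn (36.7 against 155 CPM, 0.237 [0.215–0.261]) and Daglb (9.95 against 33.8 CPM, 0.294) followed, with the proliferation genes H2ac8 (0.119), Prc1 (0.181), Ube2c (0.213), Cenpf (0.243), Birc5 (0.304) and Diaph3 (0.304). Of these, Saa3, Pcdh15, H2ac8, Ube2c, Birc5 and Diaph3 turned above 0 with doublet calls kept in and the largest cluster unnamed. With it named their log2 ratios were −2.14, −1.48, −1.44, −1.76, −1.02 and −1.26. With equal doublet removal that of Cenpf was −0.38 in place of −1.94 and that of Ube2c −0.66 in place of −2.11. Mmp13 (ENSMUSG00000050578), a collagenase gene, was highest, 153 against 15.6 CPM, ratio 9.83 [8.42–11.5], but its log2 ratio of 3.22 was 0.53 with the stricter filter and, with doublet calls kept in, 0.03 with the largest cluster unnamed and 3.26 with it named. Sparcl1 (361 against 131 CPM, 2.75 [2.60–2.92]), Hmcn2 (114 against 40.5 CPM, 2.80), Ly6h (32.0 against 9.95 CPM, 3.21) and Dchs2 (33.6 against 11.6 CPM, 2.90) were higher under every setting. Col22a1 (115 against 17.9 CPM, 6.44), Spock3 (4.81), Prph (4.51), Kirrel3 (136 against 40.7 CPM, 3.35), Rapgef4 (3.25) and Nlgn1 (2.91) were higher here but lower under at least 1 other setting, and Kcnc2 (3.51) had no counts in either library under 1. In 2 of these settings a cluster led by tenocyte markers, with Col22a1 and Nlgn1 among its leading genes, was left out of the class. It held 150 and 58 cells at resolution 2 and 125 and 47 with the stricter filter, so tenocyte-marked cells within the class moved with the group. Cells of this class had a median of 19124 UMIs in the AICAR library and 9751 in the vehicle library, and a shallow cluster held 196 and 277 of them.

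Did muscle progenitors differ? The median of commitment and fusion genes lay below 0 in myogenic progenitor-like cells, and those of the cell cycle and respiratory lists above 0. Commitment and fusion had a median of −0.37 (interval −0.66 to −0.12) with 0 higher and 9 lower of 16, such as the embryonic myosin gene Myh3 (ENSMUSG00000020908; 18.5 against 91.7 CPM, 0.202 [0.173–0.234]), Myl4 (57.9 against 172 CPM, 0.338), Mymx (59.5 against 105 CPM, 0.568) and Myog (510.1 against 674 CPM, 0.757). It was −0.10 with clusters weighted alike: cluster 26, led by Actc1 and Myog, held 50 of 529 of these cells in the AICAR library and 46 of 377 in the vehicle library. The cell cycle list had a median of 0.30 (interval 0.16 to 0.39) with 11 higher and 0 lower of 23, led by Tk1 (41.0 against 23.8 CPM, 1.72) and Pcna (158 against 111 CPM, 1.42). Mki67 (102 against 126 CPM, 0.814) did not pass the size rule. Oxidative phosphorylation had a median of 0.18 with 3 higher and 0 lower of 72 (Ndufa4 672 against 574 CPM, 1.17), glycolysis a median of 0.18 with 4 higher and 1 lower of 17 (Pkm 326 against 287 CPM, 1.14), and satellite cell identity a median of −0.21 (−0.11 with TMM factors) with 2 higher and 3 lower of 15, with Myf5 higher (197 against 152 CPM, 1.29), Hes1 lower (48.4 against 80.4 CPM, 0.602) and Pax7 at 243 against 280.1 CPM (0.867). Transcripts of immune cells moved with the group in this class. MHC class II had a median of −0.89 and neutrophil granules one of −1.25, each with 6 of 6 lower and all open to free RNA. Inflammatory genes had one of −1.05 with 2 higher and 14 lower of 20, 18 of them open to free RNA.

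Greb1 (38.2 against 6.66 CPM, 5.74), Trabd2b (5.06), Ksr2 (4.39), Ube2s (3.21) and Gstp1 (2.74) were the highest genes, and Mybph (0.179), Inpp4b (0.421) and Ucp2 (0.424) stood beside Myh3 and Myl4 as the lowest. Ube2s and Gstp1 were higher in nearly all classes. By size alone 51 genes were higher and 130 lower of 5486, and 87 and 92 with TMM factors.

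Did endothelial-like cells differ? The median of the adhesion and activation list lay above 0 with a wide interval, that of angiogenesis genes near 0, and that of cell cycle genes below 0, though not under every setting. Endothelial adhesion and activation had a median of 0.29 (interval −0.27 to 0.91) with 5 higher and 1 lower of 11: Selp (618 against 386 CPM, 1.60) and Sele (212 against 156 CPM, 1.36) were higher and Vcam1 lower (90.4 against 131 CPM, 0.690). Its median ranged from 0.07 to 0.44 over the alternatives. Among its members are Cd74 and H2-Aa, which are also MHC class II genes. Both were higher and are open to free RNA in this class. Angiogenesis and tip cell genes had a median of −0.01 and a mean of 0.07 with 3 higher and 1 lower of 16, with Apln (36.4 against 25.9 CPM, 1.40) and Angpt2 (52.3 against 37.5 CPM, 1.39) among the higher. The cell cycle list had a median of −0.61 with 2 higher and 15 lower of 23 (Top2a 35.7 against 62.3 CPM, 0.573), and turned to 0.12 for the mean of each cell's own CPM. Adamts4 (203 against 106 CPM, 1.92), Ccn2 (50.1 against 25.8 CPM, 1.95), and 2 genes higher in nearly all classes, Gstp1 (2.21) and Ube2s (1.89), were among the highest genes, and Cytl1 (3.29 against 32.3 CPM, 0.102), Prc1 (0.374), Cenpe (0.376) and Ube2c (0.435) among the lowest. For the mean of each cell's own CPM the log2 ratio was −0.54 for Prc1 (−1.37 before), −0.55 for Cenpe (−1.35), −0.60 for Ube2c (−1.15) and −2.12 for Cytl1 (−2.96). Immediate early genes had a median of 0.47 with 14 higher and 0 lower of 18. MHC class II, all 6 members open to free RNA, had one of 0.61 with 6 higher. By size alone 67 genes were higher and 68 lower of 5561, and 113 and 42 with TMM factors.

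Did T-like and NK-like cells differ? T-like cells of the AICAR library held more Cd8a, Cd8b1 and Gzmk and fewer Il13 and cell cycle transcripts. Gzmk stood at 67.4 against 4.54 CPM, ratio 14.8 [11.3–19.8], Cd8b1 at 331 against 86.2 CPM, 3.84, and Cd8a at 137 against 39.9 CPM, 3.43, with the receptor gene Trav4-4-dv10 (34.5) and Ctnna2 (10.2). Il13 stood at 13.2 against 93.9 CPM, ratio 0.141 [0.107–0.182], Lgals7 at 1.95 against 41.3 CPM, 0.0472, and the NK genes Klrb1b (0.0632), Ncr1 (8.88 against 61.7 CPM, 0.144) and Klri2 (0.144) were lower. The log2 ratio of Klrb1b was −1.61 with doublet calls kept in (−3.62 before). Those of Ncr1 and Klri2 were −1.68 and −1.58 without the cluster that came mostly from 1 library (−2.66 and −2.61 with it). MHC class II, all 9 members open to free RNA, had a median of −1.35 with 8 lower. The lipid-associated and scar-associated macrophage list had one of −0.30 with 5 lower of 12, 9 of them open to free RNA. The mix of clusters differed as well. Cluster 10, with Cd8b1 among its leading genes, held 300 of 409 T-like cells in the AICAR library and 512 of 895 in the vehicle library. Cluster 18, with Foxp3, held 89 and 288. With clusters weighted alike, the log2 ratio was 3.61 for Gzmk (3.63 without), 1.78 for Cd8b1 (1.93) and −2.33 for Il13 (−2.74). Effector and regulatory genes had a median of −0.08 with 6 higher and 9 lower of 20, with Ccl5 higher (2683 against 1388 CPM, 1.93) and Foxp3 (36.2 against 70.7 CPM, 0.512) and Gzma (261 against 600.3 CPM, 0.435) lower, and its median ranged from −0.23 to 0.08 over the alternatives. Interferon genes had a median of 0.50 (interval 0.29 to 0.66) with 14 higher and 0 lower of 20, such as Ifit3 (47.4 against 21.3 CPM, 2.23) and Rtp4 (55.9 against 37.6 CPM, 1.49).

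Glycolysis in T-like cells had a median of −0.35 with 0 higher and 10 lower of 17 (Pgk1 125 against 225 CPM, 0.555), cell cycle a median of −0.63 with 0 higher and 20 lower of 23 (Mki67 104 against 252 CPM, 0.412) and −0.24 with clusters weighted alike, and immediate early genes a median of 0.28 (0.17 without the cluster next named) with 8 higher and 1 lower of 18. A cluster of this class led by cell cycle genes carried 17 markers of T cells and 11 of NK cells and drew over 80% of its cells from the vehicle library. By size alone 84 genes were higher and 242 lower of 5109, and 117 and 194 with TMM factors.

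In NK-like cells Gzmb was higher in the AICAR library (1682 against 711 CPM, 2.37 [2.29–2.45]), as were Klra5 (35.7 against 5.34 CPM, 6.70), Klf2 (293 against 136 CPM, 2.16) and Gstp1 (2.40), the last as in nearly all classes. St6galnac3 (54.5 against 135 CPM, 0.404), Camk4 (0.416), Dscam (0.451), Stmn1 (0.462) and Kit (19.3 against 40.5 CPM, 0.476) were lower. By size alone 62 genes were higher and 61 lower of 4839.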

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

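The looser naming of the fibroblast cluster was chosen only after the result was seen. The comparisons between cell classes were picked from the medians themselves, and no difference between classes was tested. The glycolysis list had median log2 ratios of −0.25 in macrophage-like cells, −0.54 in fibroblast-like cells, −0.24 in monocyte-like cells and −0.35 in T-like cells, but 0.18 in myogenic progenitor-like cells. It stood at −0.38 in neutrophil-like cells (interval −0.62 to 0.03; −0.14 with TMM factors) and at 0.02 in endothelial-like cells. Nuclear-encoded oxidative phosphorylation stood at −0.10 in macrophage-like, −0.082 in fibroblast-like, −0.085 in monocyte-like and −0.10 in T-like cells, at −0.02 in endothelial-like cells and at 0.18 in myogenic progenitor-like cells. In neutrophil-like cells it was −0.49 with 53 of 71 members lower, but 42 of the 71 are open to free RNA, and random lists there had a median of −0.19. It was −0.24 with TMM factors and −0.16 with the stricter filter, when a cluster lost its name. Cell cycle genes stood at −1.52 in fibroblast-like cells, −0.61 in endothelial-like cells and −0.63 in T-like cells, at −0.04 in macrophage-like and −0.01 in monocyte-like cells, and at 0.30 in myogenic progenitor-like cells. The endothelial value turned to 0.12 for the mean of each cell's own CPM, and the T-like value was −0.24 with clusters weighted alike. These medians compare 2 libraries within each class, the cause of the opposite directions was not tested, and the fibroblast cell cycle value with doublet calls kept in was 0.03 with its largest cluster unnamed and −1.02 with it named.

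Barcodes over the mitochondrial limit of 10% were not analysed further. They made 6.27% of the AICAR library and 5.35% of the vehicle library, so slightly unequal parts of the libraries were left out.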

How the results depend on the processing

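The tests behind 6 alternatives were chosen only after the results were seen: equal doublet removal, combined clusters, clusters weighted alike, the smaller denominator, and 2 looser naming rules. A value counts as the same inside the 95% interval of the main value, as reversed if it changed sign (a share, the side of 1) and that interval lay on 1 side, and otherwise as moved; a median whose interval spans 0 can thus change sign without counting as reversed. Over all alternatives 1253 log2 ratios of named genes stayed the same, 400 moved and 25 reversed. Of list medians 739 stayed, 52 moved and 4 reversed, and of shares 133 stayed, 15 moved and 1 reversed. The shares of NK-like cells (0.396 to 0.444), T-like cells (0.488 to 0.532) and myogenic progenitor-like cells (1.48 to 1.63) kept their size throughout. Macrophage glycolysis ranged from −0.27 to −0.17 and the macrophage inflammatory list from 0.12 to 0.27. No paired analysis was possible because each group is 1 pooled library.

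With at least 500 genes and at most 5% mitochondrial UMIs, the ratio of shares was 1.11 for macrophage-like (1.01 before), 0.867 for neutrophil-like (0.648) and 1.60 for fibroblast-like cells (1.44). A neutrophil cluster then lost its name as shallow; with it named these ratios were 1.11, 0.675 and 1.60. Fibroblast log2 ratios reversed for Spock3 (−1.18), Prph (−0.64), Kirrel3 (−0.45) and Rapgef4 (−0.018), that of Hsp90aa1 in myofibre-like cells was 0.25, and those of erythroid-like cells were 0.49 for Isg15, 1.46 for Gadd45a, 0.81 for Apol11b and 0.66 for Rsad2, in a class nearly all changed, since only 24 of the 800 erythroid-like cells passed this filter and 23 kept the name.

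With doublet calls kept in, the macrophage share ratio was 1.12 and the fibroblast share ratio reversed to 0.851. By construction this comes from the largest fibroblast cluster losing its name, since only 34.2% of the fibroblast-like cells kept it. In the class left over, 1365 genes were higher by size alone in place of 160, the TGF-beta median was 1.22, the cell cycle median 0.033 and the contractile median 0.091. Log2 ratios there were −2.19 for Col22a1, −0.99 for Nlgn1, 0.11 for H2ac8, 0.27 for Saa3, 0.12 for Ube2c, 1.20 for Pcdh15, 0.12 for Birc5 and 0.032 for Diaph3. The macrophage NRF2 median was −0.0099, in a class that held 60.8% of the former cells. When a cluster left unnamed for its first gene alone was given its name, the fibroblast share ratio was 1.56, the macrophage one 1.12, the fibroblast cell cycle median −1.02 and the contractile one −0.63.

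The macrophage share ratio was 1.08 at Leiden resolution 0.5, 1.11 at resolution 2, 1.12 with 4000 variable genes and 50 components, and 1.10 with erythroid and unnamed clusters out of the denominator. Resolution 2 also gave log2 ratios of 0.53 for Arg1 in monocyte-like cells and, in fibroblast-like cells, −0.24 for Col22a1, −0.44 for Kirrel3, −0.78 for Prph and −1.13 for Spock3. With 4000 variable genes Arg1 in monocyte-like cells was 1.05 and Hsp90aa1 in myofibre-like cells 0.46. The boundary between the classes moves with the clustering. At resolution 2 a cluster led by Cxcl10 and Ifit2 was named monocyte (699 and 279 cells of the AICAR and the vehicle library). With 4000 variable genes a cluster led by Ifit2 and Cxcl10 was as well (1034 and 791 cells). In the main clustering such a cluster stayed unnamed. How much of the changes in monocyte-like cells this naming explains was not tested.

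In the combined clusters 16 genes were lower in place of 33, the interferon median was 0.76 and that of oxidative phosphorylation −0.081. The mean of each cell's own CPM gave 497 higher fibroblast genes, an endothelial cell cycle median of 0.12 and a log2 ratio of 0.068 for Tnfrsf12a in myofibre-like cells. Without a minimum count, 778 fibroblast genes were higher and 1028 lower, and 268 macrophage genes were higher and 114 lower. In cells thinned to 3000 UMIs 400 fibroblast genes were higher, the TGF-beta median was 0.25 and macrophage oxidative phosphorylation −0.12. Thinning left out 91 and 79 macrophage-like and 145 and 181 fibroblast-like cells of the AICAR and the vehicle library.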

Other observations

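Smaller classes showed their own differences between the AICAR and the vehicle library. The tests with equal doublet removal and with clusters weighted alike were chosen only after the results had been seen. In dendritic-like cells, Ifit3 (35.1 against 13.6 CPM, 2.57), Ifit2 (49.8 against 21.2 CPM, 2.35), Gstp1 (2.59) and Ube2s (2.39) were higher, Ifit3 in 3 of 4 clusters and Ifit2 in 2, and Cd209e (14.7 against 46.0 CPM, 0.319), Ccl17 (0.385), Syn3 (0.366), Kazn (0.412) and Zmynd15 (0.442) were lower. Gstp1, also named in Schwann-like cells below, and Ube2s were higher in nearly all classes. Ccl17 was lower in 1 of 4 clusters, with a log2 ratio of −0.43 in thinned cells (−1.33 before). With clusters weighted alike that of Zmynd15 was −0.59 (−1.14) and that of Syn3 −0.84 (−1.37). By size alone 52 of 4865 genes were higher and 50 lower, and 72 and 36 with TMM factors. Mural-like cells had more Lgr5 (38.9 against 9.53 CPM, 4.08), Ccn2 (106 against 32.0 CPM, 3.32) and Fdps (2.35) and less H2ac8 (0.149), Angptl4 (14.5 against 55.3 CPM, 0.262), Nav2 (0.278), Enpp2 (0.294) and H2ac24 (0.310). The log2 ratio was 0.30 for Fdps (1.19 before) and −0.34 for Enpp2 (−1.69) in thinned cells. It was −0.70 for Nav2 (−1.79) and −1.26 for H2ac8 (−2.58) with the stricter filter, and −0.28 for H2ac24 (−1.64) with equal doublet removal. There 62 of 5729 genes were higher and 158 lower, and 95 and 115 with TMM factors. Schwann-like cells (1.05% against 0.868%, ratio 1.21 [0.906–1.63]) had more Cntf (139 against 50.8 CPM, 2.75), Pappa (5.09), Hdx (3.21), Gstp1 (2.93) and Kirrel3 (2.52) and less Cxcl10 (37.6 against 142 CPM, 0.266), Angptl4 (0.266), Eya3 (0.320), Drp2 (0.359) and H1f2 (0.390), with 225 genes higher and 401 lower of 6198, and 327 and 286 with TMM factors. In thinned cells the log2 ratio was 0.18 for Kirrel3 (1.33 before) and 0.90 for Pappa (2.28), and for the mean of each cell's own CPM 0.93 for Hdx (1.64). With equal doublet removal it was −1.16 for Cxcl10 (−1.88), −0.75 for Eya3 (−1.61) and −0.59 for H1f2 (−1.34).

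In B-like cells of the AICAR library Vpreb1a stood at 116 against 0.775 CPM, ratio 149 [26.2–5939] from 1 count in the vehicle library, and Lef1 at 165 against 6.20 CPM, 26.5 [13.2–62.5], with Agbl1 (4.86), Gclc (3.20) and Egr1 (3.09). Wdr89 (0.290), Serpini1 (0.385), Scarb2 (0.440), Coro2a (0.440) and Snrnp25 (0.454; log2 ratio −0.30 in thinned cells, −1.11 before) were lower, and 255 genes were higher and 250 lower of 4944. Myofibre-like cells (2.79% against 1.56%, ratio 1.78 [1.46–2.18]) had Myl3 at 122 against 0 CPM, 22.6-fold over a floor of 3 counts with an exact lower limit of 18.0, and Myl2 at 157 against 1.80 CPM, 86.9 [15.3–3458] from 1 count. Cxcl10 (133 against 3.61 CPM, 36.8 [9.95–308] from 2 counts), Actc1 (2.80) and Ankrd2 (2.77) were higher, and Cyb5r3 (47.8 against 584 CPM, 0.0819), Mtss2 (0.239), Alpk3 (0.274), Tnfrsf12a (0.319) and Hsp90aa1 (0.336) lower. For the mean of each cell's own CPM the log2 ratio was 1.88 for Cxcl10 (4.86 before), −0.78 for Mtss2 (−2.05), −1.04 for Alpk3 (−1.85) and 0.068 for Tnfrsf12a (−1.63). That of Hsp90aa1 (−1.56) turned to 0.46 with 4000 variable genes. There 259 of 3176 genes were higher and 654 lower, and 496 and 439 with TMM factors, which moved all genes by a log2 of 0.20. Erythroid-like cells (5.00% against 2.96%, ratio 1.69 [1.47–1.96]) had Fam220a (ENSMUSG00000118332; 1.89), Lars2 (1.64), Isca1 (1.53), Gphn (1.41) and Cmss1 (1.36) highest and Isg15 (0.562), Gadd45a (0.681), Apol11b (0.745), Rsad2 (0.758) and Dnajb6 (0.781) lowest. The first 4 of these 5 were higher with the stricter filter, but the class then held mostly other cells. It had 155 and 119 cells, while only 24 of 800 erythroid-like cells passed the filter and 23 kept the name. With the main settings, 14 genes were higher and 1 lower of 234 by size, and 12 and 4 with TMM factors. Mast-like or basophil-like cells numbered 9 and 26.

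Of the tests that follow, the search for shared sequence, the weighting of clusters, the comparison of the combined cells with NK-like cells and the range over alternatives were chosen only after the results had been seen. Of 7324 genes with at least 50 UMIs in at least 10 of 13 classes, 13 were shifted the same way in at least 10 classes, 9 higher (such as Gstp1, Ube2s, H2ac18 and mt-Nd4l) and 4 lower (such as Rpl10-ps3 and Slc15a2) in the AICAR library, a definition set after a stricter one had been seen. Reads shared between near-identical copies are in line with 8 of the 12 genes that have a sequence, since 8 share at least 20% of the 50-base words of their last 300 bases with another gene, against a median of 2 in random sets of genes, whose 95% range ends at 4. Among the 8 are H2ac18 (100% of words shared), mt-Nd4l (98.8%), Rpl10-ps3 (88.8%) and Gstp1 (53.0%). For the 4 genes under 20%, Ube2s (12.5%) among them, shared reads stay open, because the genome sequence of the build was not searched. An effect of AICAR in every class stays open with 1 library per group.

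Type I interferon genes were higher in the combined cells, while several genes that interferon gamma induces were among the lowest in macrophage-like cells, a class that leaves out the cluster led by interferon genes. A lower response to interferon gamma was tested with further targets, which had a median log2 ratio of −0.20 in the combined cells (0 higher and 4 lower of 13, percentile 0.06). This met the rule written beforehand, although the interval over members, −0.43 to 0.19, spans 0. The median was −0.67 in macrophage-like cells (−0.97 to −0.43, 11 of 13 lower) and −0.56 in monocyte-like cells (−1.16 to −0.28, 10 of 13 lower). Both classes leave out the interferon cluster, so the size depends on where that cluster is placed. A different mix of clusters is not settled as the whole cause: with clusters weighted alike, the type I list kept a median of 0.38 (0.21 to 0.64) in the combined cells. Free RNA as the source in neutrophil-like cells did not meet its prediction, because the list added 3945 summed CPM there against at most 37.7 in fibroblast-like, endothelial-like, mural-like and myogenic progenitor-like cells and 478 in myofibre-like cells, the other class of few UMIs per cell. It is not excluded. The summed CPM fell in mural-like (−610), fibroblast-like (−60.6) and myogenic progenitor-like cells (−57.2), and a fall of their own transcripts could hide added free RNA. No profile of free RNA was estimated.

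NK-like, T-like and neutrophil-like cells took a smaller share of the AICAR library. An equal loss of all immune classes does not describe these 2 libraries, because the share ratio of the combined monocytes and macrophages was 2.74 [2.46–3.06] times that of NK-like cells. This value restates the 2 share ratios given above (1.12 and 0.409), and its rule was set after they were known. The interval covers counting error only, so the comparison is a description and not an independent test. Unequal doublet removal is excluded as the cause for NK-like cells, whose share ratio was at most 0.444 (lowest 0.396) under every alternative, with doublet calls kept in and equal removal among them. The cell filters are not settled in this way, because the only other filter tried was stricter. Barcodes over the mitochondrial limit were never put back. Those with under 200 genes were nearly all red-cell barcodes. A difference between the 2 pools or captures, and not the treatment, stays open with 1 library per group.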
